A study of Mus musculus with 6 samples.

How the data were processed

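Total RNA of 6 sorted cell samples from 3 mice was labelled with Affymetrix kits and profiled on expression arrays, 1 array per sample. The array model is not given in the sources used here. Per the labels' protocols, the mice carried Cre at the lysozyme locus, the tibialis anterior muscle had been injured with cardiotoxin 2 days earlier, CD45-positive cells were taken with magnetic beads, and the cells were sorted by Ly6C and F4/80. The same protocols give Trizol extraction and 150 ng of RNA amplified and labelled per array. The deposited values are log2 expression values made by the authors with RMA (background correction, quantile normalization and probe set summary), per the submitters' processing notes. The software, its version and its settings are not given in the sources used here, and the log2 scale was taken from the range of the values. Each array holds 35556 probe sets with 0 missing values. RMA compresses low signals, so differences of weakly expressed genes are understated. Arrays give no read depth, and background was judged from olfactory and vomeronasal receptor genes, a level that was set after the values were seen.

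Probe sets were named from the gene annotation given with the values. Of the 35556 probe sets 21789 had 1 gene symbol, 1621 had several and 12146 had none there, and only those with 1 symbol were tested as genes. The Entrez identifier of 21698 was found in the RefSeq gene table of assembly GRCm38.p6, used for names alone, 91 kept the symbol of the annotation and 0 symbols changed. No coordinates are given because no build is named for the values. Each of the 19938 symbols was represented by the probe set with the highest mean over all 6 arrays, a choice that concerned the 999 symbols with more than 1. Genes named by no such probe set are not analysed here. Ly6c1 and Ly6c2 have only shared probe sets and were tested among all 35556 probe sets.

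Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust), with no filter on level, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes. A 2-fold difference also needed an absolute log2 difference of at least 1. The tests were two-sided and the arrays are separate samples of 3 mice. The 34 gene lists, 22 programs and 12 cell types, were chosen before the data were examined, as were the design, the groups and most alternatives. They hold 832 entries, of which 767 were measured, covering 689 different genes, so lists share members. Lists were tested together with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, each with Benjamini-Hochberg adjustment over the 34 lists. fry's p tests whether the genes of a list move, on balance, one way, and does not compare the list with other genes.

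Genes were named by a rule chosen before the data were examined. It takes Ly6c1, Ly6c2, Adgre1 and Ptprc, and the 12 largest called positive and 12 largest called negative differences with the same sign in all 3 mice, leaving out predicted, RIKEN, olfactory, vomeronasal, immunoglobulin, T cell receptor and small RNA genes. It adds up to 4 called members of each list with the largest differences, 2 in each direction where both occur, and Nr4a1, Pparg, Ccr2, Cx3cr1, Il1b, Tnf, Il10, Tgfb1, Igf1, Arg1 and Mrc1 whatever their result. This gave 144 genes with probe sets of their own. The results describe a part of them. They leave out 9 whose call was lost without 1 array, of which Cma1, Pou2af1 and Siglecf appear only where the block ended their calls.

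The labels give both subsets from the same animal, so the mouse number pairs the arrays. The deviations of the paired arrays of mice 1, 2 and 3 from their subset means correlated at 0.03, -0.08 and 0.09 across genes, and the consensus correlation within a mouse was -0.01. No source states a paired test, so the fit without the mouse as a block was the main one and the block an alternative. The other alternatives were the mouse as a random effect, quantile normalization, a common median, filters that left out 25% or 50% of genes by level, the mean of a gene's probe sets, all probe sets tested separately, a trended robust prior, array weights, and leaving out each array and each mouse. Cyclic loess normalization and a filter at the 95th percentile of the olfactory and vomeronasal receptor genes were added after seeing the data.

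The gene and list tests were tested on simulated data with 200 changed genes among 19938. They recovered 68.7% of genes changed by 0.5 on the log2 scale, 98.5% of those changed by 1 and 100.0% of those changed by 2, with 7 false calls among 185. With no gene changed there were 0 calls. A list shifted by 0.5 was called and 0 of the other 33 were. The simulation changed 200 genes, against 6748 called in the data, so its recovery and false calls need not hold there. The simulated genes were independent of each other, so the simulation did not test lists whose members vary together. In the real data the estimated correlation within a list reached 0.64, for glycolysis and hypoxia genes.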

Results

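Gene expression was measured in 2 macrophage subsets sorted from injured mouse muscle. The tibialis anterior muscle was injured by cardiotoxin, a snake toxin that kills muscle fibres and starts regeneration, and cells were taken on day 2. CD45-positive blood-lineage cells were separated and sorted by the antigens Ly6C and F4/80 into a Ly6C+ F4/80low and a Ly6C- F4/80high subset. Both subsets came from each of 3 mice, giving 6 arrays with 3 per subset. The comparison asks how the 2 subsets differ within the regenerating muscle. Arrays of the same subset correlated at 0.990 to 0.993 across probe sets. Arrays of different subsets correlated at 0.979 to 0.982, and probe sets are not independent replicates. The first principal component carried 77.9% of the variance and separated the subsets, and the second carried 6.75%. The number of arrays limits the precision of every value. All differences below are Ly6C- F4/80high minus Ly6C+ F4/80low on the log2 scale, with 3 arrays per subset and the standard error in parentheses. All adjusted p-values of single genes are from limma. The background was taken as 5.44, the 95th percentile of the levels of olfactory and vomeronasal receptor genes. Where all 3 arrays of a subset lay under it, the difference is a bound, with those arrays set to the background.

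The genes of the sorting antigens followed the gates. The probe sets shared by Ly6c1 and Ly6c2, the genes of the Ly6C antigens, cannot tell these genes apart. They averaged 8.02 ± 0.25 (SD, n = 3) in the Ly6C- F4/80high cells and 11.4 ± 0.12 (SD, n = 3) in the Ly6C+ F4/80low cells on 1 shared probe set, 10.5-fold lower (limma adjusted p = 9.79e-05 over all probe sets), and were 9.08-fold lower on the other. Adgre1, which encodes F4/80, was higher by 0.73 (SE 0.07, limma adjusted p = 4.46e-05). Ptprc, which encodes the CD45 used for bead selection, differed by -0.64 (SE 0.07, limma adjusted p = 0.000127). These genes check the labels and are no finding of the comparison.

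Atp6v0d2, Htr2b and Npl had the largest measured differences toward the Ly6C- F4/80high cells. Atp6v0d2, a subunit of the proton pump that acidifies lysosomes, was 14.7-fold higher, by 3.88 (SE 0.08, limma adjusted p = 5.11e-09). The serotonin receptor gene Htr2b followed at 3.82 (SE 0.14), with 1 of 3 Ly6C+ F4/80low arrays above the background, and Npl, an enzyme of sialic acid breakdown, at 3.30 (SE 0.10). Igf1, a growth factor for muscle, averaged 10.2 ± 0.07 (SD, n = 3) against 6.94 ± 0.22, a difference of 3.25 (SE 0.11). Serpinb6a, an intracellular protease inhibitor, was higher by 3.24 (SE 0.10), and the chemokine gene Ccl8 by 3.08 (SE 0.10). Cd5l, a secreted macrophage protein of the scavenger receptor family, was not above background in the Ly6C+ F4/80low cells and at least 3.89-fold higher in the others. The lipid phosphatase gene Plpp3 differed by 2.75 (SE 0.14), the ubiquitin ligase gene Rnf128 by 2.65 (SE 0.11) and Lpl, which encodes lipoprotein lipase, by 2.60 (SE 0.10). The paraoxonase gene Pon3 was higher by 2.57 (SE 0.07) and Tbc1d19, of the TBC-domain family, by 2.53 (SE 0.07), with 2 of 3 Ly6C+ F4/80low arrays above the background.

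Ly6a2, Serpinb10 and Ifitm6 had the largest measured differences toward the Ly6C+ F4/80low cells, a rank that for Ly6a2 and Serpinb10 rests on values under the background. Serpinb10, a protease inhibitor, was not above background in the Ly6C- F4/80high cells and at least 16.3-fold lower there (limma adjusted p = 3.83e-09). Ifitm6, of the interferon-induced transmembrane family, differed by -4.91 (SE 0.13) and Plac8, a gene of blood monocytes, by -4.65 (SE 0.13). Vcan, the gene of the matrix proteoglycan versican, averaged 7.12 ± 0.08 (SD, n = 3) against 11.5 ± 0.05, a difference of -4.37 (SE 0.08). Ly6a2, also not above background in the Ly6C- F4/80high cells, was at least 33.8-fold lower, a value that stays uncertain because related Ly6 genes could bind its probes. The same held for the adhesion receptor gene Adgre4, at least 5.16-fold lower, and the lectin-like receptor gene Klra2, at least 7.04-fold lower. The orphan receptor gene Gpr141, above background on 1 of 3 Ly6C- F4/80high arrays, differed by -2.77 (SE 0.13) and Trem3, an activating myeloid receptor, by -2.61 (SE 0.10). Slfn4 of the Schlafen family, the paired immunoglobulin-like receptor gene Pilrb1 and the membrane protein gene Ms4a4c differed by -2.58 (SE 0.10), -2.52 (SE 0.11) and -2.49 (SE 0.08). Klra2, Pilrb1, Slfn4 and Ms4a4c belong to families of similar sequence, so probes may read several members.

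**Figure D1:**
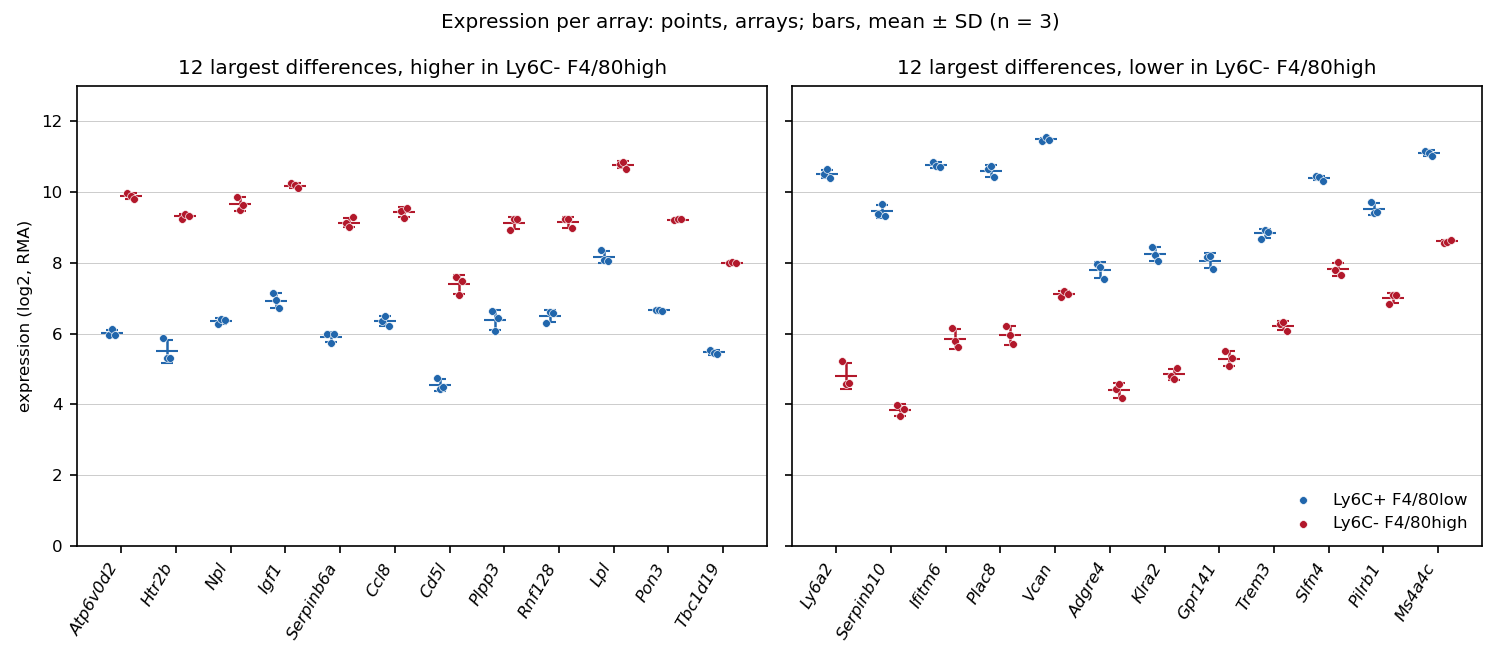
Log2 expression of the 12 genes with the largest positive and the 12 with the largest negative difference; points are single arrays, horizontal bars the mean and error bars the SD of the 3 arrays of a subset (blue, Ly6C+ F4/80low; red, Ly6C- F4/80high). The arrays of the 2 subsets do not overlap for any gene shown, as for Igf1 with means of 10.2 and 6.94.

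In all, limma called 6748 of 19938 genes, of which 3887 were higher and 2861 lower in the Ly6C- F4/80high cells. These were 19.5% and 14.3% of all genes, and counts of list members near these shares are no sign of a shift. At least 2-fold differences were called for 583 genes, 380 higher and 203 lower, and all 583 had the same direction in each of the 3 mice. The excess of higher genes depended on the scaling, with 302 higher and 247 lower 2-fold genes after quantile normalization and 308 and 245 after cyclic loess. Among all called genes 3152 were higher and 2960 lower after quantile normalization, and 3282 and 2752 after cyclic loess. With a common median the excess was larger, with 402 higher and 196 lower 2-fold genes, and 4069 and 2589 among all called genes. Called differences of at least 4-fold numbered 32 higher and 29 lower. The arrays of the subsets did not overlap for 48.1% of genes, against 10% expected by chance with 3 against 3. The median size of a called difference was 0.43 on the log2 scale. Without mouse 3 the number of called genes was 3998, while 577 passed the 2-fold threshold.

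Genes of resident and phagocytic macrophages were higher in the Ly6C- F4/80high cells. Among 26 measured tissue macrophage genes 17 were higher, 2 lower and 7 not called, with a list median of 0.69 (camera adjusted p = 4.75e-08, adjusted p = 0.111 with an estimated correlation). The 17 include Adgre1, the gene of the sorting antigen F4/80. Gas6, which bridges dying cells to their receptors, was higher by 2.36 (SE 0.09), and the folate receptor gene Folr2 by 2.28 (SE 0.09). Axl, a receptor for Gas6, went the other way at -0.98 (SE 0.12). Mrc1, the mannose receptor gene, is often used to mark macrophages of repair and differed by 0.02 (SE 0.08, limma adjusted p = 0.893). Of 29 scavenger and apoptotic-cell uptake receptors 16 were higher, 4 lower and 9 not called, with a median of 0.36 (camera adjusted p = 0.00127, adjusted p = 0.111 with an estimated correlation). That median was 0.25 after quantile normalization and 0.24 after cyclic loess. Of these 29 genes 14 are also in other lists, and Gas6, Mertk, Stab1, Cd163, C1qa, C1qb and C1qc are higher members of the tissue macrophage list too. The scavenger list was led by Gas6 and by Mfge8, another bridging protein, at 1.90 (SE 0.10), while the fungal glucan receptor gene Clec7a differed by -1.51 (SE 0.09). The complement and Fc receptor genes were split, with 5 of 21 higher, 8 lower and 8 not called (median -0.01, mean 0.12, camera adjusted p = 0.859). Cd59a, an inhibitor of complement lysis, was at least 1.25-fold higher, with no Ly6C+ F4/80low array above background (1.15-fold without the Ly6C- F4/80high array of mouse 1). C1qa, which starts the classical pathway, was higher by 1.55 (SE 0.08), whereas Cfb, of the alternative pathway, differed by -1.30 (SE 0.09). The median of this list fell on the other side of zero from its mean and its test.

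Lysosomal and lipid genes showed the same direction. Lysosome genes were higher in 26 of 32 cases, lower in 2 and not called in 4, with a median of 0.49 (camera adjusted p = 2.37e-10, adjusted p = 0.111 with an estimated correlation). The protease gene Ctsk was higher by 1.31 (SE 0.11), whereas Gm2a, a ganglioside-binding cofactor, and Ctsc, a dipeptidyl peptidase, differed by -0.48 (SE 0.07) and -0.46 (SE 0.08). Among 28 sterol and lipid handling genes 18 were higher, 5 lower and 5 not called (median 0.61, camera adjusted p = 6.66e-05, adjusted p = 0.129 with an estimated correlation). The largest of the higher members were Lpl and Cd36, the fatty acid receptor gene, at 1.57 (SE 0.08). Those that were lower included the sterol synthesis gene Idi1 at -1.10 (SE 0.11) and Insig1, a sterol sensor of synthesis control, at -0.81 (SE 0.07). Iron and heme handling genes were higher in 11, lower in 4 and not called in 8 of 23 cases, with a median of 0.16 (camera adjusted p = 0.0217, adjusted p = 0.148 with an estimated correlation). Tfrc, the transferrin receptor gene, was higher by 1.32 (SE 0.12), while the haptoglobin gene Hp was 4.01-fold lower and the lipocalin gene Lcn2 differed by -1.78 (SE 0.14). This list was no longer called without the 25% of genes of lowest level (median 0.35, adjusted p = 0.0736) or the 50% of lowest level (median 0.44, adjusted p = 0.121), though its median was then larger.

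Proliferation and respiration genes were also higher in the Ly6C- F4/80high cells. Of 39 cell cycle genes 32 were higher, 1 lower and 6 not called, with a median of 0.80 (camera adjusted p = 4.17e-15, adjusted p = 0.0499 with an estimated correlation). Mcm6, of the replicative helicase, was higher by 1.83 (SE 0.10). Ccna2, the cyclin A gene of DNA replication and mitotic entry, and the topoisomerase gene Top2a were not above background in the Ly6C+ F4/80low cells and at least 3.53-fold and 2.26-fold higher in the others. Ccnd2, a cyclin of the early cycle, differed by -0.53 (SE 0.09). Oxidative phosphorylation genes were higher in 25 of 31 cases and not called in 6, and none was lower (median 0.40, camera adjusted p = 3.58e-10, adjusted p = 0.111 with an estimated correlation). The shift was smaller after quantile normalization, with 20 higher (median 0.32), and after cyclic loess, with 21 higher (median 0.28). Cyc1, of respiratory complex III, was higher by 0.67 (SE 0.08), Sdhb, of complex II, by 0.63 (SE 0.07) and Ndufa1, of complex I, by 0.57 (SE 0.08). Glycolysis and hypoxia genes went the other way, with 1 of 22 higher, 11 lower and 10 not called (median -0.41, camera adjusted p = 0.0129, adjusted p = 0.573 with an estimated correlation). The oxygen-sensing hydroxylase gene Egln3 differed by -1.94 (SE 0.29), the lactate exporter gene Slc16a3 by -1.52 (SE 0.13) and Ankrd37, a target of hypoxia signalling, by -1.10 (SE 0.19), whereas the hexokinase gene Hk3 was higher by 0.81 (SE 0.08). The glycolysis list was no longer called without mouse 2 (adjusted p = 0.0606) or with fry (adjusted p = 0.0986). With the mouse as a replicate block 13 of its members were lower, adding the kinase genes Pfkfb3 (adjusted p = 0.0121) and Hk2 (adjusted p = 0.0250), which are named here after their values were seen.

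Interferon and antigen presentation genes were mostly lower in the Ly6C- F4/80high cells, and inflammatory genes in part. All 23 measured interferon-stimulated genes were lower, with a median of -0.89 (camera adjusted p = 3.04e-14, adjusted p = 0.148 with an estimated correlation). The RNA-degrading Isg20 differed by -1.62 (SE 0.08), the antiviral synthetase gene Oas2 by -1.39 (SE 0.08), the regulator gene Irf7 by -1.29 (SE 0.08) and the antiviral GTPase gene Mx1 by -1.28 (SE 0.19). Of 27 inflammatory cytokine and chemokine genes 13 were lower, 3 higher and 11 not called (median -0.22, camera adjusted p = 0.00675, adjusted p = 0.179 with an estimated correlation). Il1b differed by -1.61 (SE 0.09), and Il6, not above background in the Ly6C- F4/80high cells, was at least 1.76-fold lower there, while the chemokine genes Ccl8 and Cxcl16 were higher, by 3.08 (SE 0.10) and 0.61 (SE 0.10). Tnf, a central inflammatory cytokine, averaged 10.1 in both subsets, with a difference of -0.01 (SE 0.10, limma adjusted p = 0.929). Pattern recognition and NF-kB genes were lower in 19, higher in 4 and not called in 9 of 32 cases (median -0.40, camera adjusted p = 0.000117, adjusted p = 0.112 with an estimated correlation). Trem1, an amplifying receptor, differed by -2.25 (SE 0.15) and the DNA sensor gene Tlr9 by -1.58 (SE 0.09), whereas the RNA sensor gene Tlr8 was higher by 0.69 (SE 0.12) and the inflammasome adaptor gene Pycard by 0.69 (SE 0.08). Of 16 MHC class II and co-stimulation genes 11 were lower, 2 higher and 3 not called, with a median of -0.71 (camera adjusted p = 6.66e-05, adjusted p = 0.148 with an estimated correlation). The co-stimulatory genes Cd86 and Cd80 differed by -1.57 (SE 0.12) and -1.50 (SE 0.08), and the protease gene Ctss, which trims the invariant chain, was higher by 0.49 (SE 0.08). Dendritic cell markers were lower too in 11 of 20 cases, with a median of -0.36, though 10 of the 20 had both subset means under the background, among them 4 called ones.

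Most Ly6C-high monocyte genes were lower in the Ly6C- F4/80high cells, and the Ly6C-low monocyte genes were split. Of 17 Ly6C-high monocyte genes 12 were lower, 2 higher and 3 not called (median -0.42, camera adjusted p = 7.26e-05, adjusted p = 0.148 with an estimated correlation). Ccr2, the receptor that draws monocytes into tissue, was 3.99-fold lower (limma adjusted p = 2.41e-06), while the collagenase gene Mmp8 and the glutathione transferase gene Mgst1 were higher by 0.73 (SE 0.08) and 0.71 (SE 0.08). Of these 17 genes 9 are also in other lists, Mmp8 among the neutrophil markers, which were lower too in 8 of 23 cases (camera adjusted p = 0.00323, adjusted p = 0.228 with an estimated correlation). Of 16 Ly6C-low monocyte genes 7 were lower, 4 higher and 5 not called (median -0.27, camera adjusted p = 0.0445, adjusted p = 0.228 with an estimated correlation). Treml4, a receptor of patrolling monocytes, differed by -2.04 (SE 0.13) and Nr4a1, an orphan nuclear receptor needed for those cells, by -1.09 (SE 0.07), whereas Cd36 and the fatty acid carrier gene Fabp4 were higher by 1.57 (SE 0.08) and 1.47 (SE 0.10). Cx3cr1, the fractalkine receptor gene of the same cells, differed by -0.40 (SE 0.18, limma adjusted p = 0.111), and was called after quantile normalization (-0.56, adjusted p = 0.0371) and cyclic loess (-0.55, adjusted p = 0.0452). Its difference was -0.82 in mouse 1, -0.12 in mouse 2 and -0.27 in mouse 3. The Ly6C+ F4/80low array of mouse 1 stood at 8.90, those of mice 2 and 3 at 8.15 and 8.14. The Ly6C-low list was no longer called without the Ly6C+ F4/80low array of mouse 1 (median -0.14, adjusted p = 0.0623) or mouse 2 (adjusted p = 0.0516), without the Ly6C- F4/80high array of mouse 2 (adjusted p = 0.0892), without mouse 2 (adjusted p = 0.106), or with array weights (adjusted p = 0.0540).

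Transcription factor genes shifted in both directions. Of 39 macrophage and monocyte transcription factor genes 19 were lower, 5 higher and 15 not called, with a median of -0.26 (camera adjusted p = 0.0130, adjusted p = 0.228 with an estimated correlation). Bhlhe41, a repressor of the circadian helix-loop-helix family, was higher by 2.28 (SE 0.13) and Cebpa, a myeloid lineage factor, by 0.82 (SE 0.12), while Runx3 and Id3 differed by -1.03 (SE 0.11) and -0.92 (SE 0.16). This list was no longer called without the Ly6C- F4/80high array of mouse 2 (adjusted p = 0.0528) or without mouse 2 (adjusted p = 0.0852). Of 29 nuclear receptor genes 8 were lower, 6 higher and 15 not called, and the list was not called (median -0.07, camera adjusted p = 0.604). The vitamin D receptor gene Vdr differed by -1.69 (SE 0.13) and the orphan receptor gene Nr4a2 by -1.13 (SE 0.10), whereas Rxra, the common partner of many nuclear receptors, was higher by 0.86 (SE 0.08) and Nr2c1 by 0.74 (SE 0.08). Pparg, a lipid-sensing receptor, averaged 9.29 ± 0.07 (SD, n = 3) against 9.17 ± 0.02, a difference of 0.12 (SE 0.07, limma adjusted p = 0.218).

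Growth factor and alternative activation genes did not move as blocks. Of 21 repair growth factor genes 9 were higher, 4 lower and 8 not called (median 0.07, camera adjusted p = 0.0250, adjusted p = 0.228 with an estimated correlation). Besides Igf1, Pdgfc, a platelet-derived growth factor gene, was higher by 2.31 (SE 0.12), and the activin subunit gene Inhba differed by -1.16 (SE 0.13). Tgfb1, a regulator of fibrosis and resolution, differed by -0.20 (SE 0.14, limma adjusted p = 0.291), and by -0.43 (adjusted p = 0.0426) without mouse 1. The growth factor list was no longer called without the Ly6C+ F4/80low array of mouse 1 (adjusted p = 0.0636) or without mouse 1 (adjusted p = 0.0598). Its call was also lost without the 25% (median 0.27, adjusted p = 0.0798) or 50% (median 0.36, adjusted p = 0.119) of genes of lowest level, though the median was then larger. Its median was -0.03 without the Ly6C- F4/80high array of mouse 2, 0.12 without that of mouse 1 and 0.12 without that of mouse 3. Of 20 alternative activation genes 8 were lower, 3 higher and 9 not called (median -0.18, camera adjusted p = 0.0610). Arg1, which encodes arginase 1, was higher by 1.36 (SE 0.29, limma adjusted p = 0.00462), with an SD of 0.72 in the Ly6C+ F4/80low cells and an adjusted p of 0.0507 when the variance prior followed the level and was robust. The hemoglobin receptor gene Cd163, not above background in the Ly6C+ F4/80low cells, was at least 1.34-fold higher. The decoy receptor gene Il1r2 differed by -2.33 (SE 0.09), the chemokine gene Ccl24 by -1.33 (SE 0.11) and Il10, the anti-inflammatory cytokine gene, by -0.61 (SE 0.12). This list was called without the Ly6C+ F4/80low array of mouse 1 (adjusted p = 0.0382), its Ly6C- F4/80high array (adjusted p = 0.0175) or both (adjusted p = 0.0122). It was also called without the 50% of genes of lowest level (adjusted p = 0.00261), with the filter at the olfactory receptor level (adjusted p = 0.0174) and with the trended robust prior (adjusted p = 0.0390).

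Matrix, adhesion and secretory stress genes differed in part. Of 30 extracellular matrix and proteolysis genes 14 were lower, 10 higher and 6 not called (median -0.21, camera adjusted p = 0.366). Timp2, a protease inhibitor, was higher by 2.04 (SE 0.09) and the coagulation factor gene F7 by 1.33 (SE 0.12), while Vcan and the matrix protein gene Sparc differed by -4.37 (SE 0.08) and -2.03 (SE 0.14). Of 35 fibroblast and endothelial markers 26 were lower too, and like their mean Sparc was highest in the Ly6C+ F4/80low cells of mouse 1, at 8.85. Of 28 chemokine receptor and adhesion genes 14 were lower, 7 higher and 7 not called (median -0.24, camera adjusted p = 0.0620). The integrin gene Itgal, of the leukocyte adhesion receptor LFA-1, differed by -2.48 (SE 0.08), whereas the tetraspanin gene Cd9 and the laminin-binding integrin gene Itga6 were higher by 1.89 (SE 0.09) and 1.66 (SE 0.09). That list was called after quantile normalization (adjusted p = 0.0294), after cyclic loess (adjusted p = 0.0181), without the Ly6C- F4/80high array of mouse 1 (adjusted p = 0.0426) and without mouse 1 (adjusted p = 0.0370). The same held without the 50% of genes of lowest level (adjusted p = 0.00768), with the filter at the olfactory receptor level (adjusted p = 0.0227) and with the trended robust prior (adjusted p = 0.0378). Of 22 protein secretory stress genes 11 were lower, 1 higher and 10 not called (median -0.19, camera adjusted p = 0.0131, adjusted p = 0.402 with an estimated correlation). Herpud1, of endoplasmic reticulum protein degradation, differed by -1.32 (SE 0.11), Asns, an amino acid synthesis gene, by -0.71 (SE 0.13) and the chaperone gene Creld2 by -0.64 (SE 0.09). The secretory stress list was no longer called without mouse 2 (adjusted p = 0.0591).

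Markers of other cell types that the bead selection or the gates could hold were checked in 12 lists, and none was called higher in the Ly6C- F4/80high cells. Of 18 fibroblast markers 14 were lower and 4 not called (median -0.41, camera adjusted p = 1.93e-05, adjusted p = 0.296 with an estimated correlation), with Pi16 at -1.23 (SE 0.15), above background on 1 of 3 Ly6C- F4/80high arrays. The proteoglycan genes Dcn and Bgn were not above background in those cells and at least 1.49-fold and 1.87-fold lower, limits that rest on the Ly6C+ F4/80low array of mouse 1, without which they fell from 0.57 to 0.18 and from 0.90 to 0.59 on the log2 scale. Of 17 endothelial markers 12 were lower, 2 higher and 3 not called (median -0.49, camera adjusted p = 0.00128, adjusted p = 0.228 with an estimated correlation). The junction gene Cdh5 differed by -1.51 (SE 0.10) and the surface sialomucin gene Emcn, above background on 2 of 3 Ly6C+ F4/80low arrays and on 0 of the others, was at least 1.21-fold lower (1.08-fold without the Ly6C+ F4/80low array of mouse 1), whereas Fabp4 and the TGF-beta co-receptor gene Eng, at 0.70 (SE 0.08), were higher. The 26 fibroblast and endothelial markers called lower averaged 6.14 in the Ly6C+ F4/80low cells of mouse 1, 5.88 and 5.87 in those of the other mice, and between 5.23 and 5.37 in the Ly6C- F4/80high cells. Of 23 neutrophil markers 8 were lower, 1 higher and 14 not called (median -0.18, camera adjusted p = 0.00323, adjusted p = 0.228 with an estimated correlation). Hdc, the histamine-forming enzyme gene, differed by -2.38 (SE 0.14) and the neutrophil surface antigen gene Cd177 by -2.25 (SE 0.11). Of 20 dendritic cell markers 11 were lower, 2 higher and 7 not called (median -0.36, camera adjusted p = 0.00127, adjusted p = 0.148 with an estimated correlation), with the lectin gene Cd209a at -1.19 (SE 0.08) and Cd24a higher by 0.43 (SE 0.10). Both subset means lay under the background for 10 of the 20, among them 4 called ones.

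The remaining cell types gave small or mixed shifts. Of 16 NK cell markers 4 were lower and 12 not called (median -0.20, camera adjusted p = 0.0130, adjusted p = 0.296 with an estimated correlation). Of 14 mast cell and basophil markers 4 were lower and 10 not called (median -0.23, camera adjusted p = 0.0130, adjusted p = 0.331 with an estimated correlation), led by Hdc. Quantile normalization ended the calls of the NK cell list (adjusted p = 0.157) and the mast cell list (adjusted p = 0.116), as did cyclic loess (adjusted p = 0.136 and 0.0922), and the NK cell list was not called without the 25% of genes of lowest level (adjusted p = 0.126). T cell markers were lower in 4, higher in 2 and not called in 12 of 18 cases (median -0.20, camera adjusted p = 0.100), with the co-receptor gene Cd28 higher by 0.57 (SE 0.11) and Cd3e at -0.45 (SE 0.09). B cell markers were higher in 3, lower in 2 and not called in 12 of 17 cases (median -0.13, mean 0.07, camera adjusted p = 0.645). Their higher members Blnk, a signalling adaptor, and Cd22, a sialic acid receptor, differed by 1.97 (SE 0.09) and 1.38 (SE 0.10), and the B cell list was called higher without the 50% of genes of lowest level (median 1.38, adjusted p = 0.0139). Eosinophil markers had 1 higher, 2 lower and 6 not called of 9 (median -0.10, camera adjusted p = 0.478). Erythroid and platelet markers had 2 higher and 7 not called of 9 (median -0.08, mean 0.13, camera adjusted p = 0.989), Pf4, a chemokine of platelets and macrophages, at 1.38 (SE 0.15) and Gypc at 0.71 (SE 0.15). Of 20 myofibre markers 2 were higher, the enolase gene Eno3 at 0.64 (SE 0.10) and Cox6a2 at 0.52 (SE 0.08), and 18 were not called (median -0.04, mean 0.01, camera adjusted p = 0.989). Of 15 myogenic cell markers 2 were lower and 13 not called (median -0.14, camera adjusted p = 0.0581), with Pax7, of muscle stem cells, at -0.35 (SE 0.08), a call lost without mouse 3 (-0.30, adjusted p = 0.0718). The myogenic list was called without the Ly6C- F4/80high array of mouse 2 (adjusted p = 0.0294), without mouse 2 (adjusted p = 0.0395), without the 25% of genes of lowest level (adjusted p = 0.0447), or without the Ly6C+ F4/80low array of mouse 3. Of the NK cell markers 15 of 16 lay near the background, among them all 4 called ones, where differences of this size are not distinct from it, as did 11 of 14 mast cell and basophil markers. The receptor gene Klrk1, the ribonuclease gene Ear6 and the lineage factor gene Ebf1, called lower, lay under the background on all arrays, so no size is given. The B cell, erythroid and myofibre lists had medians, means and tests that differed in sign.

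**Figure D2:**
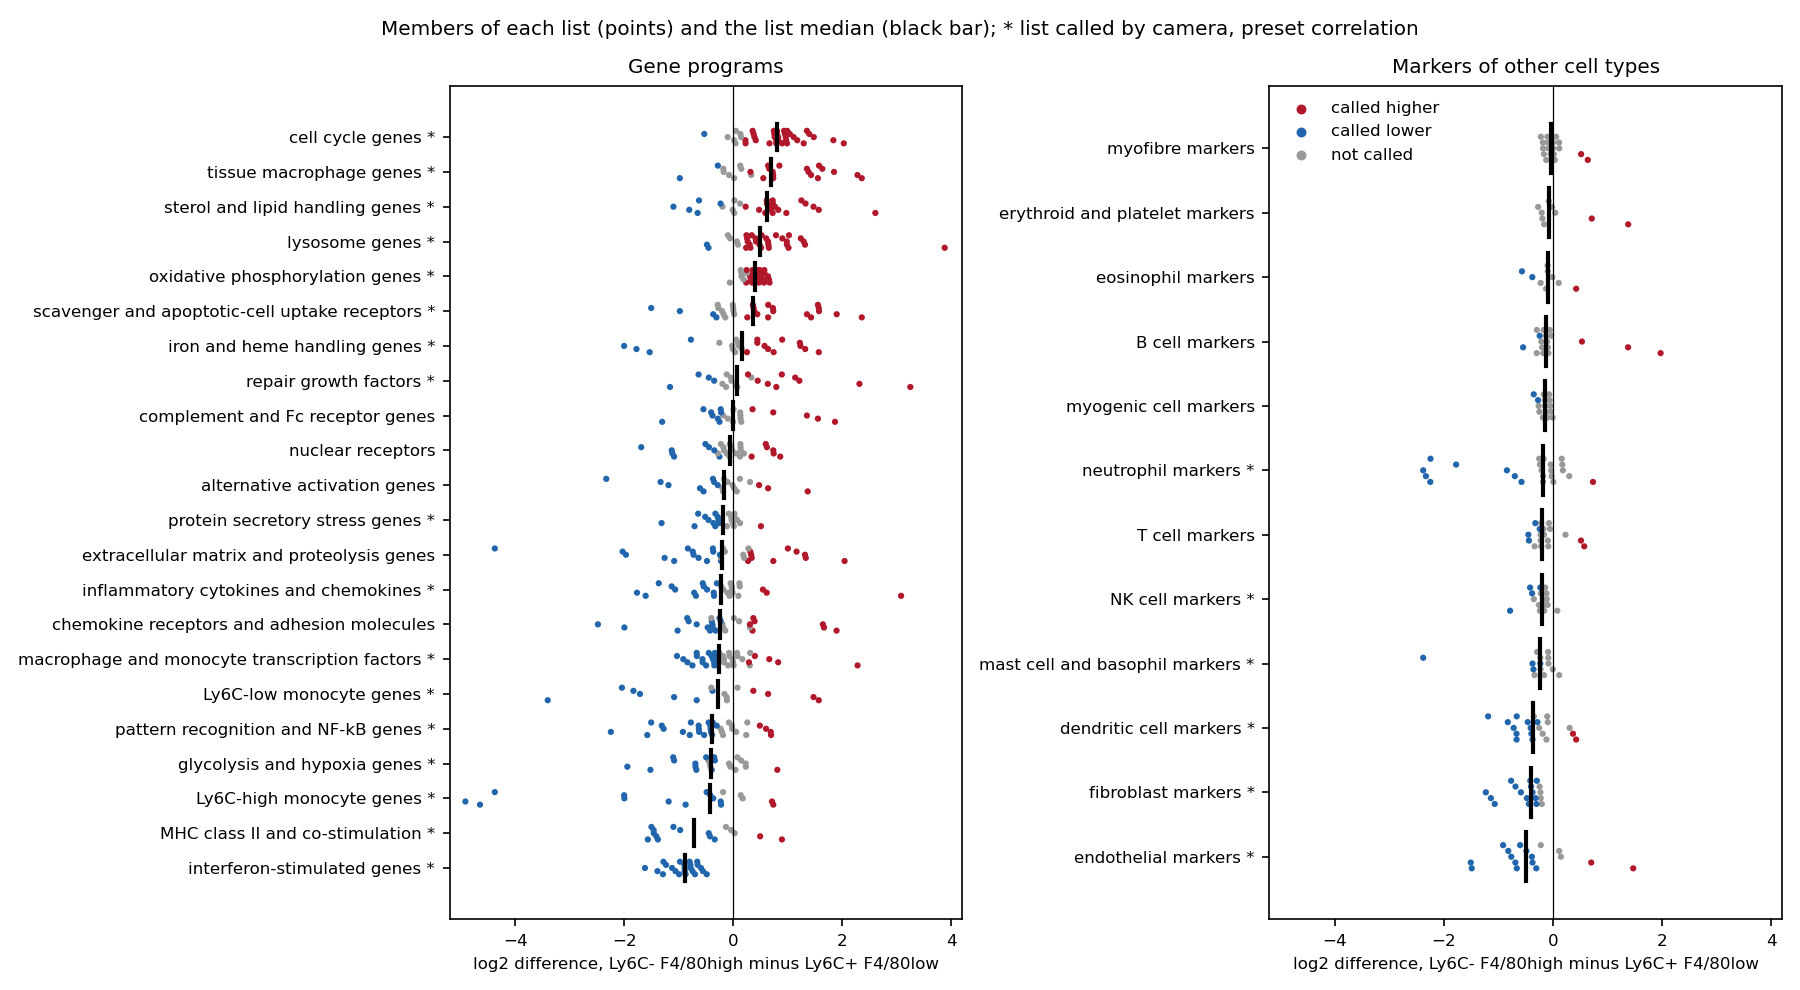
Log2 difference (Ly6C- F4/80high minus Ly6C+ F4/80low) of every measured member of the 34 lists; points are genes coloured by the limma call, black bars list medians, and asterisks mark lists called by camera with the preset correlation. All 23 interferon-stimulated genes lie below zero and 32 of 39 cell cycle genes are called above it.

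Of the 34 lists 23 were called, 8 higher and 15 lower, and 1 was called with an estimated correlation. With fry 29 were called, 9 higher and 20 lower. With the mouse as a replicate block 22 lists had members whose call changed, at most 4 in a list, for oxidative phosphorylation with 21 of 31 then higher. The same list test called between 5 and 13 lists in the other splits of the 6 arrays, in which limma called 0 genes, with 128 to 903 genes at an unadjusted p under 0.05. Those splits mix arrays of both subsets unevenly, so they keep part of the subset difference. Adjusted over the list alone, the counts of called members were the same in 22 lists. They were otherwise 18 higher and 2 lower for tissue macrophage genes, 1 and 12 for glycolysis and hypoxia, 27 and 0 for oxidative phosphorylation, 18 and 6 for sterols and lipids, and 16 and 6 for scavenger receptors. Further such counts, adjusted over the list alone, were 5 higher and 20 lower for pattern recognition, 6 and 21 for transcription factors, 8 and 15 for chemokine receptors and adhesion, 1 and 9 for neutrophil, 3 and 13 for dendritic cell, 0 and 15 for fibroblast and 2 and 13 for endothelial markers.

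Olfactory and vomeronasal receptor genes, which macrophages are not known to use, gave a measure of the background. These 1190 genes had a median level of 3.62 and a 95th percentile of 5.44. Of them 199 were called, 194 lower in the Ly6C- F4/80high cells, with a median of -0.16 over all 1190, so differences of that size at low levels are not distinct from the background. After quantile normalization 97 were called, 85 lower, with a median of -0.07. Both subset means lay under 5.44 for 7180 genes, of which 995 were called and 6 differed at least 2-fold. The median difference was -0.11 in the 25% of genes of lowest level and 0.11 in the 25% of highest level. The Ly6C- F4/80high arrays had the wider spread of values, with an upper quartile between 7.81 and 7.82 against 7.63 to 7.65.

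**Figure D3:**
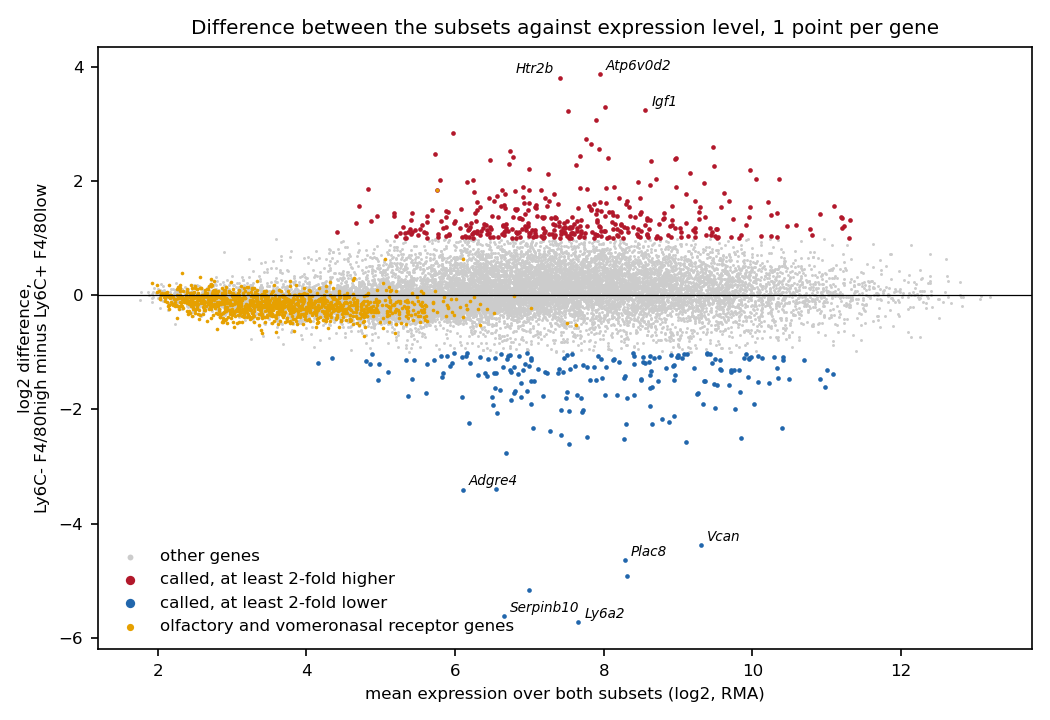
Log2 difference (Ly6C- F4/80high minus Ly6C+ F4/80low) against mean log2 expression, 1 point per gene; red and blue mark the 380 and 203 genes called at least 2-fold higher or lower, orange the 1190 olfactory and vomeronasal receptor genes. The orange points centre on -0.16 at low levels. Some of the largest differences, such as those of Ly6a2 and Serpinb10, have a Ly6C- F4/80high mean under the background level.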

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

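Cyclic loess and the filter at the olfactory receptor level were chosen after seeing the data, the other alternatives before. Across all alternatives that keep the 6 arrays, the number of called genes lay between 5720 and 7048 and that of 2-fold genes between 517 and 598, with 754 2-fold probe sets when all were tested separately. With the mouse as a replicate block 6164 genes were called, 584 of them 2-fold, and of the named genes and lists the block ended the calls of Cma1 (adjusted p = 0.0567), Pou2af1 (adjusted p = 0.0580) and Siglecf (adjusted p = 0.0553) and changed no other of their calls. Leaving out arrays or mice gave 3998 to 6887 genes, lowest without mouse 3, where each subset kept 2 arrays. For list tests an estimated correlation left 1 of 23 calls, cell cycle genes. Of 144 named genes 120 kept direction and call in every setting they were tested in. Reversed signs concerned results that were not called in the main fit, and the cause was not tested. Among the reversed results, only the B cell list without the lowest 50% of genes was called. Tnf was 0.0099 with a common median, 0.0026 with array weights, and between -0.0987 and 0.0447 without single arrays or mice. Mrc1 was -0.0030 after quantile normalization, -0.0290 after cyclic loess, and between -0.0543 and 0.0919 without arrays or mice. Lists reversed in the direction of their test, and the values are their medians. Complement genes had -0.18 without the lowest 25% of genes, and -0.20 both without the lowest 50% and with the filter at the olfactory level. B cell markers had -0.0342 after quantile normalization, -0.0211 after cyclic loess, -0.11 without the lowest 25%, -0.0606 with the olfactory filter and -0.13 with fry, and 1.38 without the lowest 50% (adjusted p = 0.0139), where few members were left. For erythroid and platelet markers they were -0.0769 without the lowest 25%, -0.0180 with the olfactory filter, -0.0774 with array weights, and between -0.1850 and 0.0041 without arrays or mice. For myofibre markers the medians were 0.0059 after quantile normalization, -0.0143 with a common median, 0.0249 after cyclic loess, 0.0326 without the lowest 50%, -0.0369 with fry, and between -0.0823 and -0.0076 without arrays or mice.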

Other observations

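The gene families below, the test of other cell types for the cell cycle genes, the test of shared deviations of stromal markers, the neutrophil test and the cyclic loess tests were chosen after the values were seen, and the other tests before. Gene families picked for their values were compared with all genes. Of 32 genes of DNA replication factors (the Mcm, Orc, Gins, Pola, Pole, Prim and Rfc families) 30 were higher in the Ly6C- F4/80high cells and 2 were not called, with a median of 0.68 (26 higher and 0 lower after cyclic loess). Rfc4, of the complex that loads the sliding clamp, was higher by 1.16 (SE 0.11). Of 10 acyl-CoA dehydrogenase genes, of fatty acid or branched-chain amino acid breakdown, 8 were higher, among them Acadm at 0.82 (SE 0.08), and of 21 vacuolar proton pump genes 12 were higher and 2 lower, among them Atp6v0a1 at 0.98 (SE 0.09). These families held more genes called higher than the 19.5% of all genes (Fisher's exact test, two-sided, adjusted over the 8 families, p = 1.19e-18, 0.000102 and 0.000199 in that order), though genes are not independent. The families were picked for these same values, so the p-values describe the choice and are no test of enrichment.

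The other families picked held more genes called lower than the 14.3% of all genes, in differing measure. They too were picked for their values, so the p-values below are no test of enrichment. Of 8 guanylate-binding protein genes, which encode interferon-induced GTPases, 7 were lower (Fisher's exact test, adjusted p = 3.48e-05), with Gbp9 at -1.20 (SE 0.08). Of 9 genes of the interferon-activated 200 family of DNA sensors 7 were lower (Fisher's exact test, adjusted p = 6.86e-05), with Ifi205 at -1.91 (SE 0.16). Of 11 C-type lectin genes of the Clec4 family 8 were lower (Fisher's exact test, adjusted p = 5.22e-05), with Clec4n, the gene of Dectin-2, at -2.16 (SE 0.08). Of 9 Schlafen genes 5 were lower (Fisher's exact test, adjusted p = 0.00527), and of 19 Ms4a genes 7 were lower, 2 higher and 10 not called (Fisher's exact test, adjusted p = 0.0129). Of these genes 4 of 8 guanylate-binding, 3 of 9 of the 200 family, 4 of 11 Clec4 and 9 of 19 Ms4a genes lay near the background, where small negative differences are not distinct from it. Members of these families resemble each other in sequence, so single probe sets can read several of them. Among the olfactory receptor genes Olfr111, singled out after its value was seen, was at least 2.37-fold higher, at 6.68 ± 0.46 (SD, n = 3), and not above background in the Ly6C+ F4/80low cells.

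The cell cycle genes were higher in the Ly6C- F4/80high cells with a median of 0.80. If the wider spread of values on those arrays were the cause, cyclic loess should remove the difference, but the median was then 0.85, and the lowest median without 1 mouse was 0.79. Of the 12 lists of other cell types 0 were called higher in that sort, which does not exclude cells of a listed type, since Pf4 (1.38) and Gypc (0.71) were higher. B cell markers went both ways, 3 higher (Blnk at 1.97, Cd22 at 1.38), 2 lower and 12 not called (adjusted p = 0.645), with the B cell lineage gene Ms4a1 near the background at 3.76 against 3.80, and their call without the 50% of genes of lowest level (median 1.38, adjusted p = 0.0139) leaves out the weakly expressed members. Other cell types and a higher share of dividing macrophages both stay open, and RNA levels do not measure division.

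The fibroblast and endothelial markers were lower in the Ly6C- F4/80high cells, although CD45 beads should remove such cells. The wider spread of values is not the whole cause, since 24 of the 35 measured markers were called lower after cyclic loess, against 26 in the main fit. Stromal cells or their RNA in the Ly6C+ F4/80low sort could be a source, and the 35 measured markers then vary together between arrays of 1 subset. Their deviations correlated at 0.31 on average, against a median of 0.05 and a 95th percentile of 0.14 in 10000 random lists matched on level, of which 0 reached the observed value. Random genes share no program, so this cannot tell stromal cells from genes regulated together. The correlation estimated by camera was 0.50 for fibroblast and 0.18 for endothelial markers, so the shared variation was larger among the fibroblast markers. It was 0.64 for glycolysis and hypoxia, 0.42 for interferon-stimulated and 0.01 for cell cycle genes. In the Ly6C+ F4/80low sort Cdh5 stood at 7.82 and Col1a1 at 6.99, 3 of the list genes occur in other lists, Ly6c1 is itself an endothelial gene, and a real subset difference stays open.

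Neutrophil-associated genes were lower in the Ly6C- F4/80high cells in part. The test assumed that neutrophils in the Ly6C+ F4/80low sort would bring all their abundant transcripts. S100a8, S100a9, Retnlg, Ngp, Camp and Ltf had a median difference of -0.10, against -2.25 for Hdc, Il1r2, Cd177, Trem1 and Lcn2, which were picked for their low values. Whether neutrophils of injured muscle express all of the first 6 genes was not measured, so their median alone does not decide. S100a9 alone was called lower among these, and was not above background in the Ly6C- F4/80high cells. In the Ly6C+ F4/80low cells S100a8 stood at 6.06, S100a9 at 5.78 and Retnlg at 4.43, near the background of 5.44. Of the 23 measured neutrophil markers 7 belong to other lists too, and Hdc, Il1r2 and Trem1 may be genes of the Ly6C+ F4/80low macrophages themselves, which was not tested further.

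With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split was 1 of 10 in the number of called genes (6748, highest other 0, where limma gave up to 903 genes at an unadjusted p under 0.05), 1 of 10 in 2-fold calls (583, highest other 0) and 1 of 10 in called lists (23, highest other 13). The other 3 splits that also part every pair from the same mouse gave 0 genes and 8, 10 and 13 lists. Each other split mixes arrays of both subsets unevenly, so it keeps part of the subset difference and widens the spread within its groups. Its 0 gene calls and its list calls are therefore no measure of chance. The list test with a preset correlation made calls where no gene was called, and whether those were false cannot be told here. A call of a list rests on the counts of its members as much as on its p. Those counts are to be read against the 19.5% of all genes called higher and the 14.3% called lower.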
